A study of Mus musculus with 33 samples.

How the data were processed

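The series measured RNA in 33 libraries of follicular (FO) and marginal zone (MZ) B cells sorted from the spleen of Tsc1F.hCD20-TamCre mice, in which tamoxifen activates a Cre recombinase in B cells and Cre deletes floxed Tsc1 exons. Mice were 12 weeks old and had received tamoxifen 4 weeks earlier. The labels name SMART-Seq HT cDNA and Nextera XT libraries, whereas the series text names a polyA capture method from the 3' end. Per the series text, the authors quantified transcripts with kallisto, normalized with voom and tested with limma. The processing notes name mm10 as the genome. Versions, the transcript annotation, any filter and any pooling of animals were not stated.

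The deposited tables hold 29995 genes without immunoglobulin genes and 30317 with them. The deposited normalized values are on a log2 scale, of the form voom gives: an estimated count, scaled for transcript length, plus 0.5, divided by the library total plus 1. The deposited TPM tables hold transcript abundance corrected for length. The library totals implied by both tables differed from the sums of the implied counts by at most 0.0677%. These totals, called estimated reads below, ran from 2.77 to 9.71 megareads per library.

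Groups came from the labels: Tsc1+/+ with Cre (WT), FL/+ (het) and FL/FL (KO) for each cell type. Genes with a TPM of at least 1 in at least 5 libraries were tested, which left 20513. The test was limma 3.58.1 in R 4.3.3 with a mean-variance trend and robust moderation, in 1 model of 6 group means over all 33 libraries. It was two-sided, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05. The 8 comparisons were KO with WT, het with WT and KO with het in each cell type, MZ WT with FO WT, and the difference between the KO effects of MZ and FO cells. Log2 changes are given as the first group minus the second, ± SE, and TPM as mean ± SD. Each FO group held 5 libraries and each MZ group 6.

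The 40 gene lists covered metabolism, growth and stress pathways, B cell states, and markers of other cell types. Each list was tested with camera, which compares a list with all other tested genes, at a preset correlation of 0.01, adjusted over the lists of a comparison. The same test with an estimated correlation is given beside it, and 54 of 171 list calls of the preset test held under it. Counts of members past the threshold are given over all tested genes and adjusted over the list alone.

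Genes were named by a rule. Tsc1 and Tsc2 were always included. For KO with WT in each cell type and for MZ WT with FO WT, the 8 largest rises and 8 largest falls were taken among called genes whose groups did not overlap and whose mean was at least 5 TPM in the higher group. For the other comparisons of 2 groups the same rule took 3 and 3. For the difference of KO effects it took 5 and 5 with a mean of at least 5 TPM in the highest group. From each list up to 4 called members with the smallest p were taken. Predicted genes, pseudogenes, mitochondrial, immunoglobulin and small RNA genes were skipped in the ranking. The groups, the tests of these comparisons, the lists and this rule were chosen before the data were examined, as were the alternatives other than those named below as added.

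The share of TPM taken by immunoglobulin genes and a score of MZ-like expression were compared between groups by exact permutation tests, two-sided. The score was the mean log2 value of genes higher in MZ WT than in FO WT minus that of genes lower, over the genes called in that comparison. Gene positions came from GENCODE vM21 (GRCm38), in which 28162 of the 29995 symbols (93.9%) were found. Background signal was read from 1665 genes of the olfactory receptor, vomeronasal receptor, keratin-associated and defensin families. Libraries were taken as male at a Ddx3y level of at least 20 TPM, a limit raised from 1 TPM after the values were seen.

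The pipeline was run on simulated data, 100 of 20513 genes per shift, with no rate for weakly expressed genes. Of those shifted by 0.5 on the log2 scale, it recovered 37% for KO with WT in FO and 50% in MZ, 42% and 46% for het with WT, 30% and 39% for KO with het, 45% for MZ with FO WT, and 19% for the difference. At a shift of 1, these were 88% and 80%, 84% and 87%, 73% and 83%, 79%, and 62%. False calls were 3 to 13.

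Alternatives changed the fold minimum, pseudocount, scaling, gene filter, weights, moderation, groups in the model, replicate block, library left out, list correlation and controls. A mean of at least 20 TPM, a background term, a sex term, weights from estimated counts and leaving out MZ WT 1 with FO KO 6 were chosen after seeing the data. Splits of the same libraries into other groups were drawn up to 100 times. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 and the R package data.table, version 1.17.8, handled tables and figures.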

Results

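RNA was profiled in FO and MZ B cells, sorted as CD19+CD93−CD23+CD21/35int and CD19+CD93−CD23−CD21/35high. Tsc1 encodes a partner of Tsc2 in the complex that restrains mTORC1, the kinase complex that couples nutrients to growth. The design asked what loss of 1 or both Tsc1 alleles does to the transcriptome of each cell type. There were 5 libraries each of FO WT, FO het and FO KO, and 6 each of MZ WT, MZ het and MZ KO. The labels do not say whether libraries with the same number came from 1 animal, so p-values measure spread between samples. Megareads, as estimated, averaged 5.00 ± 1.38 in FO WT, 4.44 ± 1.27 in FO het, 6.06 ± 1.73 in FO KO, 6.73 ± 1.301 in MZ WT, 7.87 ± 0.473 in MZ het and 8.89 ± 0.696 in MZ KO. Y-linked Ddx3y marked 1 FO WT, 3 FO het, 3 FO KO, 2 MZ WT, 4 MZ het and 3 MZ KO libraries as male.

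Libraries differed in a low signal over genes that B cells do not express. Olfactory receptor and similar genes averaged 1.10 ± 0.378 TPM in FO WT, 0.852 ± 0.280 in FO het, 0.843 ± 0.412 in FO KO, 0.493 ± 0.260 in MZ WT, 0.124 ± 0.0258 in MZ het and 0.138 ± 0.0683 in MZ KO. MZ WT 1 stood at 0.0383 TPM and the other MZ WT libraries at 0.432 to 0.751, and FO KO 6 at 0.248. With it went the number of genes at 1 TPM or more, from 17879 ± 1798 in FO WT to 14915 ± 1893 in MZ WT and 12176 ± 249 in MZ het. The median log2 change of all tested genes was -0.24 for KO with WT in FO and -0.40 in MZ, -0.11 and -0.30 for het with WT, -0.34 for MZ with FO WT, -0.09 and -0.01 for KO with het, and -0.13 for the difference of KO effects. Scaling to equal medians moved these by 0.34, 0.59, 0.24, 0.61, 0.48, 0.10, -0.02 and 0.25, and quantile normalization by 0.25, 0.63, 0.12, 0.60, 0.47, 0.05, 0.02 and 0.24. Median scaling adds 1 constant to all genes of a comparison, so it turns any negative change smaller than that. Genes with a mean of at least 5 TPM had medians of -0.07, 0.01, -0.03, -0.01, 0.02, -0.04, 0.05 and 0.05 without any such scaling.

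**Figure D1:**
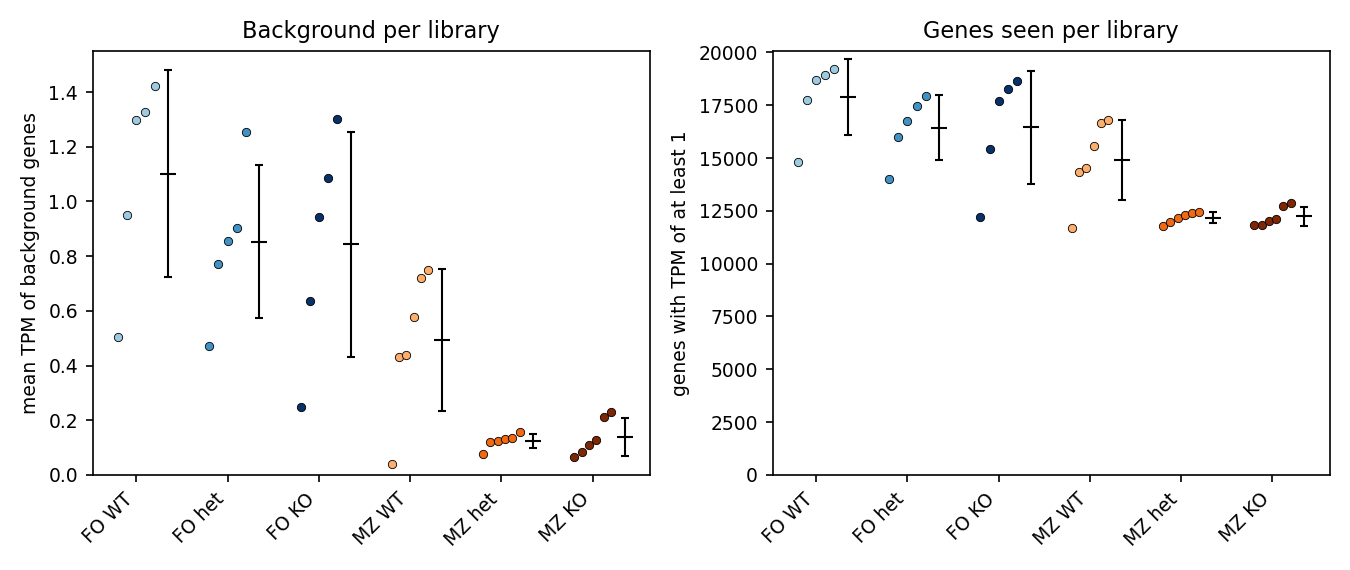
Left, mean TPM of olfactory receptor and similar genes per library; right, number of genes with a TPM of at least 1 per library, for the 6 groups. Points are libraries and bars are mean ± SD; MZ het and MZ KO average 0.124 and 0.138 TPM on the left against 1.10 in FO WT.

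Tsc1 (chromosome 2, 28641228 to 28691167, plus strand of GRCm38) had gene-level means of 15.3 to 23.5 TPM in the 6 groups, which checks nothing about the deletion, since the floxed exons are only part of the transcript. Its TPM was 24.0, 21.7, 20.4, 19.4 and 28.4 in FO WT 1, 3, 4, 5 and 6, then 17.5, 20.4, 24.5, 13.1 and 16.2 in FO het 1, 2, 3, 4 and 6, and 25.4, 18.4, 21.2, 14.9 and 19.3 in FO KO 2 to 6. In MZ libraries 1 to 6 it was 17.8, 15.8, 19.7, 17.4, 20.3 and 13.8 in WT, 21.8, 14.05, 13.6, 14.9, 14.6 and 13.2 in het, and 22.0, 24.1, 26.1, 18.3, 26.8 and 24.0 in KO. Tsc1 rose from MZ het to MZ KO (15.3 ± 3.24 to 23.5 ± 3.07 TPM, log2 0.55 ± 0.14, adjusted p = 0.00677). It did not pass the test for KO with WT in FO (log2 -0.20 ± 0.15, adjusted p = 0.492) or in MZ (log2 0.36 ± 0.14, adjusted p = 0.0517), and the latter reached an adjusted p of 0.0314 to 0.0486 without FO WT 6, FO het 3, FO het 4, FO KO 2, FO KO 5, FO KO 6, MZ WT 1, MZ WT 5, MZ het 1 or MZ KO 4. For het with WT its values were log2 -0.31 ± 0.15, adjusted p = 0.634 in FO and log2 -0.19 ± 0.14, adjusted p = 0.388 in MZ. Tsc2 (chromosome 17, 24595816 to 24632630, minus strand) was called in no comparison, with log2 -0.04 ± 0.13, adjusted p = 0.887 in FO KO and log2 0.15 ± 0.12, adjusted p = 0.327 in MZ KO against WT.

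The comparison of MZ WT with FO WT showed the identity of the sorted cells. Fcer2a, which encodes the sort marker CD23 (chromosome 8, 3681737 to 3694175, minus strand), fell from 594 ± 103 to 24.3 ± 3.40 TPM, log2 -4.56 ± 0.22, adjusted p = 5.24e-16. S1pr3, a sphingosine phosphate receptor that holds B cells in the marginal zone (chromosome 13, 51408639 to 51422797, plus strand), rose from 6.72 ± 1.94 to 140.2 ± 25.5 TPM, log2 4.44 ± 0.20, adjusted p = 2.24e-17. Dtx1, a Notch pathway gene (chromosome 5, 120680202 to 120711927, minus strand), rose from 81.8 ± 22.0 to 558 ± 58.3 TPM, log2 2.84 ± 0.11, adjusted p = 1.55e-19, and Cd1d1, which presents lipids, from 59.5 ± 15.02 to 478 ± 61.0 TPM, log2 3.07 ± 0.16, adjusted p = 5.24e-16. Of MZ B cell genes, 15 of 17 rose and 0 fell, 16 and 0 adjusted over the list alone. Their median log2 change was 2.84 (adjusted p = 9.51e-35, or adjusted p = 3.70e-07 with an estimated correlation). Of FO B cell genes, 2 of 10 rose and 8 fell, 2 and 8 adjusted over the list alone. The list had a median log2 change of -1.33 (adjusted p = 1.11e-07, or adjusted p = 0.0139 with an estimated correlation). They included Cd55, a complement regulator (log2 -2.07 ± 0.09, adjusted p = 5.21e-18), Sell, the homing receptor L-selectin (log2 -1.24 ± 0.08, adjusted p = 6.95e-14), and Itgb7, an integrin chain (log2 -2.24 ± 0.15, adjusted p = 2.71e-13).

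Other large rises in MZ WT were Ackr3, a scavenging chemokine receptor (3.07 ± 1.20 to 97.1 ± 18.7 TPM, log2 5.05 ± 0.48, adjusted p = 2.43e-09), Rap1gap, which switches off the GTPase Rap (log2 4.99 ± 0.35, adjusted p = 4.53e-13), Ackr2 (log2 4.62 ± 0.30, adjusted p = 4.24e-14), Drd5, a dopamine receptor (log2 4.80 ± 0.58, adjusted p = 7.08e-08), Ffar2, a fatty acid receptor (log2 3.90 ± 0.38, adjusted p = 6.16e-10), Ceacam2 (log2 3.91 ± 0.33, adjusted p = 3.15e-11) and Tsga13 (log2 4.50 ± 0.60, adjusted p = 5.37e-07). Crisp3, a secreted protein (log2 -3.92 ± 0.35, adjusted p = 1.37e-10), Myadm (log2 -2.85 ± 0.24, adjusted p = 4.29e-11), Wfdc17 (log2 -3.35 ± 0.30, adjusted p = 1.04e-10), Pde2a, a cyclic nucleotide phosphodiesterase (log2 -4.37 ± 0.87, adjusted p = 0.000553), and Fcgrt, the neonatal Fc receptor (log2 -4.26 ± 0.99, adjusted p = 0.00255), fell. So did Mapk12, a stress kinase (log2 -3.50 ± 0.38, adjusted p = 8.78e-09), and Cacna1i, a calcium channel subunit (log2 -3.48 ± 0.45, adjusted p = 5.30e-07). Among Notch targets 5 of 10 rose and 1 fell, 5 and 1 adjusted over the list alone. These genes had a median log2 change of 1.93 (adjusted p = 1.36e-06, or adjusted p = 0.00414 with an estimated correlation). Myc went from 254 to 1077 TPM and Hes5 from 2.09 to 17.1 TPM. Among B cell activation genes 10 of 20 rose and 4 fell, 12 and 5 adjusted over the list alone. At the median, log2 change was 0.46 (adjusted p = 3.91e-05, or adjusted p = 0.0189 with an estimated correlation). Cd86, a costimulatory ligand, went from 51.9 to 131 TPM. Mzb1, a chaperone for IgM assembly, rose from 283 to 791 TPM (log2 1.52 ± 0.09, adjusted p = 1.21e-14). Of ribosome biogenesis genes, 10 of 40 rose and 2 fell, 12 and 2 adjusted over the list alone. As a list they had a median log2 change of 0.18 (adjusted p = 3.46e-06, or adjusted p = 0.0357 with an estimated correlation), and Npm1, a nucleolar chaperone, rose from 444 to 650.3 TPM. Of immediate early genes, 14 of 25 rose and 2 fell, 17 and 2 adjusted over the list alone. List members had a median log2 change of 0.81 (adjusted p = 1.52e-10, or adjusted p = 0.0357 with an estimated correlation). Atf3 rose from 11.4 to 87.4 TPM. Of cytosolic ribosomal protein genes, 67 of 80 rose and 0 fell, 72 and 0 adjusted over the list alone. Its median log2 change was 0.41 (adjusted p = 4.98e-33, or adjusted p = 0.150 with an estimated correlation). Of cholesterol synthesis genes, 0 of 24 rose and 11 fell, 0 and 14 adjusted over the list alone, at a median log2 change of -0.45, 0.04 under median scaling and -0.45 under quantile normalization (adjusted p = 0.000119, or adjusted p = 0.0386 with an estimated correlation). Ldlr, the LDL receptor, went from 9.63 to 1.56 TPM and Sqle, a rate-limiting enzyme, from 20.9 to 7.54 TPM. Of MHC class II genes, 0 of 11 rose and 10 fell, 0 and 10 adjusted over the list alone, at a median log2 change of -0.34, 0.14 under median scaling and -0.35 under quantile normalization (adjusted p = 1.67e-06, or adjusted p = 0.150 with an estimated correlation). In total 1788 genes rose and 2102 fell, 2614 and 609 under median scaling and 2218 and 1747 under quantile normalization. Groups of 2172 genes did not overlap (1120 higher and 1052 lower), 10.6% of genes where chance gives 0.433%. The lower genes had a median mean of 6.76 TPM and the higher ones 31.2 TPM. Markers of myeloid cells were lower in MZ WT, where 0 of 18 rose and 8 fell, 0 and 8 adjusted over the list alone. Median log2 change was -0.86 (adjusted p = 0.00723, or adjusted p = 0.431 with an estimated correlation).

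In FO cells, loss of both Tsc1 alleles went with higher Apoe and lysosomal genes. Apoe, a lipid-carrying apolipoprotein (chromosome 7, 19696109 to 19699188, minus strand), rose 5.34-fold from 349.9 ± 61.6 to 1851 ± 245 TPM, log2 2.42 ± 0.15, adjusted p = 2.25e-13. Hexa, a subunit of lysosomal beta-hexosaminidase (chromosome 9, 59539540 to 59565109, plus strand), rose 3.27-fold from 88.8 ± 6.81 to 289.9 ± 29.2 TPM, log2 1.71 ± 0.08, adjusted p = 1.62e-17. Of lysosomal genes, 28 of 40 rose and 0 fell, 31 and 0 adjusted over the list alone. Across the list, median log2 change was 0.58 (adjusted p = 8.00e-55, or adjusted p = 5.43e-06 with an estimated correlation). Tpp1, a lysosomal peptidase, rose from 25.9 to 66.0 TPM, Gns, a lysosomal sulfatase, from 74.0 to 180.4 TPM, and Atp6v0c, a subunit of the lysosomal proton pump, from 254 to 440.2 TPM. Flcn, which acts on the Rag GTPases that bring mTORC1 to lysosomes (chromosome 11, 59791408 to 59810016, minus strand), rose from 47.5 ± 6.24 to 104 ± 14 TPM, log2 1.13 ± 0.11, adjusted p = 3.24e-09.

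Large rises among genes named by rank were Lilrb4 (10.9 ± 3.63 to 93.4 ± 33.5 TPM, log2 3.10 ± 0.23, adjusted p = 4.99e-12) and its paralog Gp49a (log2 2.42 ± 0.25, adjusted p = 1.55e-08), immunoglobulin-like receptors whose reads may not be separable. Others were Dok2, an adaptor of tyrosine kinase signalling (log2 2.72 ± 0.47, adjusted p = 0.000316), Hpgds, a prostaglandin D synthase (log2 2.59 ± 0.37, adjusted p = 1.40e-05), Fam167a (log2 2.44 ± 0.14, adjusted p = 5.44e-15), Hspa1a, an inducible heat shock protein (log2 2.36 ± 0.43, adjusted p = 0.000631), and Gstm1, a glutathione transferase (log2 2.26 ± 0.27, adjusted p = 2.39e-07). Dok2 was also higher in FO het, as given below for het cells. Among the falls, Vwa5a went from 16.4 ± 2.72 to 6.20 ± 2.56 TPM, log2 -1.46 ± 0.20, adjusted p = 4.17e-06, Asb2, a ubiquitin ligase subunit, from 6.56 to 2.46 TPM (log2 -1.39 ± 0.32, adjusted p = 0.00549), Kif22, a mitotic kinesin, from 8.93 to 2.88 TPM (log2 -1.53 ± 0.36, adjusted p = 0.00606), and Cldn10, a claudin, from 6.36 to 2.53 TPM (log2 -1.35 ± 0.35, adjusted p = 0.0133). The erythroid genes Kel, Gfi1b and Epor and the clone RP23-370F14.2, listed at 0 in FO KO, were also among the largest falls, and each lost its call without 1 of several libraries. Gfi1b (log2 -1.86 ± 0.51, adjusted p = 0.0228) lost it without FO WT 6, FO KO 4 or FO KO 6 (adjusted p 0.0525, 0.0650 and 0.0893), and RP23-370F14.2 without FO WT 1 or FO KO 6 (0.0924 and 0.0687). Kel (log2 -1.90 ± 0.58, adjusted p = 0.0425) lost it without FO WT 4, 5 or 6 or FO KO 3, 4 or 6 (0.0651 to 0.133), and Epor (log2 -1.66 ± 0.51, adjusted p = 0.0450) without FO WT 3, 4, 5 or 6, FO KO 2, 3, 4 or 6, MZ WT 3 or 5, or MZ KO 1, 2 or 6 (0.0502 to 0.122).

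Of mTORC1 pathway components, 7 of 31 rose and 0 fell, 8 and 1 adjusted over the list alone. By median, log2 change was 0.10 (adjusted p = 9.22e-07, or adjusted p = 4.88e-05 with an estimated correlation). Lamtor1, which anchors the Ragulator complex to lysosomes, rose from 90.2 to 163 TPM, the Rag GTPase Rragc from 37.3 to 78.7 TPM and Ddit4, an mTORC1 inhibitor, from 3.17 to 7.72 TPM. Among cholesterol synthesis genes 9 of 24 rose and 0 fell, 11 and 0 adjusted over the list alone. For the list, median log2 change was 0.42 (adjusted p = 6.41e-12, or adjusted p = 0.000444 with an estimated correlation). Fdps rose from 35.4 to 59.2 TPM, Fdft1 from 11.7 to 18.6 TPM and Hmgcs1 from 21.0 to 30.9 TPM. Of ATF4 targets, 6 of 25 rose and 0 fell, 8 and 1 adjusted over the list alone. In log2, the median change was 0.16 (adjusted p = 1.98e-05, or adjusted p = 0.0773 with an estimated correlation). Of cytosolic aminoacyl-tRNA synthetases, 4 of 20 rose and 1 fell, 7 and 2 adjusted over the list alone. The median log2 change was 0.15 (adjusted p = 0.000185, or adjusted p = 0.0773 with an estimated correlation). Phgdh, the entry enzyme of serine synthesis, rose from 95.6 to 201 TPM and the stress factor Ddit3 from 77.5 to 149.5 TPM. Sars, the synthetase for serine, rose from 85.4 to 157 TPM. Of immediate early genes, 9 of 25 rose and 0 fell, 13 and 1 adjusted over the list alone. Their median log2 change was 0.61 (adjusted p = 2.79e-15, or adjusted p = 0.0119 with an estimated correlation). Btg2 (272 to 518 TPM), Atf3 (11.4 to 35.1 TPM) and Jun (202 to 404 TPM) were among them. Of FoxO-associated genes, 5 of 20 rose and 2 fell, 7 and 3 adjusted over the list alone. The list had a median log2 change of 0.19 (adjusted p = 0.00181, or adjusted p = 0.0458 with an estimated correlation). Of migration receptors, 7 of 25 rose and 2 fell, 9 and 4 adjusted over the list alone. These genes had a median log2 change of 0.18 (adjusted p = 8.71e-05, or adjusted p = 0.0280 with an estimated correlation). S1pr1, the egress receptor, rose from 159 to 295 TPM, Pik3ip1, a PI3K inhibitor, from 87.8 to 211 TPM, and Bcl6, the germinal centre repressor, fell from 46.1 to 27.1 TPM. Of oxidative phosphorylation genes, 12 of 78 rose and 3 fell, 26 and 3 adjusted over the list alone. At the median, log2 change was 0.21 (adjusted p = 5.33e-17, or adjusted p = 0.116 with an estimated correlation). Of proteasome genes, 9 of 40 rose and 0 fell, 12 and 0 adjusted over the list alone. As a list they had a median log2 change of 0.13 (adjusted p = 1.54e-09, or adjusted p = 0.0749 with an estimated correlation).

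Among MZ B cell genes in FO cells 3 of 17 rose and 5 fell, 3 and 6 adjusted over the list alone, at a median log2 change of -0.27, 0.07 under median scaling and -0.25 under quantile normalization (adjusted p = 0.439, or adjusted p = 0.723 with an estimated correlation). S1pr3 (6.72 to 16.7 TPM) and Dtx1 (81.8 to 129 TPM) rose, whereas Cr2, which encodes CD21 and CD35 (321 to 208 TPM), and Cd1d1 (59.5 to 31.5 TPM) fell. Of FO B cell genes, 2 of 10 rose and 0 fell, 2 and 0 adjusted over the list alone. List members had a median log2 change of 0.13 (adjusted p = 0.00329, or adjusted p = 0.138 with an estimated correlation). The list's p was 0.0515 without FO KO 6. Its risers were Klf2, a migration and quiescence factor (59.4 ± 31.4 to 230.4 ± 152 TPM, log2 1.91 ± 0.44, adjusted p = 0.00653), and Itgb7 (173 to 287 TPM). Hes1, a Notch target, rose from 9.85 to 35.2 TPM, and Klf2 and Hes1 belong to a block of 16 genes that varied together between libraries of 1 group. Of cytosolic ribosomal protein genes, 0 of 80 rose and 20 fell, 0 and 43 adjusted over the list alone, at a median log2 change of -0.27, 0.07 under median scaling and -0.28 under quantile normalization (adjusted p = 4.22e-13, or adjusted p = 0.357 with an estimated correlation). Rpsa (934 to 664 TPM) and Rpl18a (2993 to 2083 TPM) fell. Of cell cycle genes, 0 of 36 rose and 15 fell, 0 and 29 adjusted over the list alone. Its median log2 change was -0.67 (adjusted p = 5.21e-11, or adjusted p = 0.147 with an estimated correlation). Tk1 (37.9 to 17.5 TPM) and Mcm7 (62.8 to 40.6 TPM) fell. Cd24a, high in immature B cells, fell from 316 to 178 TPM. Pdcd1lg2, a ligand of PD-1, rose from 10.8 to 34.9 TPM and Nme1, a nucleotide kinase, from 71.7 to 153 TPM. Among T cell markers 0 of 17 rose and 3 fell, 0 and 5 adjusted over the list alone. Median log2 change was -0.84 (adjusted p = 0.000175, or adjusted p = 0.107 with an estimated correlation). Trbc1 went from 20.9 to 7.87 TPM. In total 690 genes rose and 585 fell, 142 and 125 of them by at least 2-fold. The split was 233 and 13 under median scaling and 910 and 503 under quantile normalization. Groups did not overlap for 561 higher and 516 lower genes, 5.25% where chance gives 0.794%. Leaving out 1 library gave 954 to 1343 genes.

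**Figure D2:**
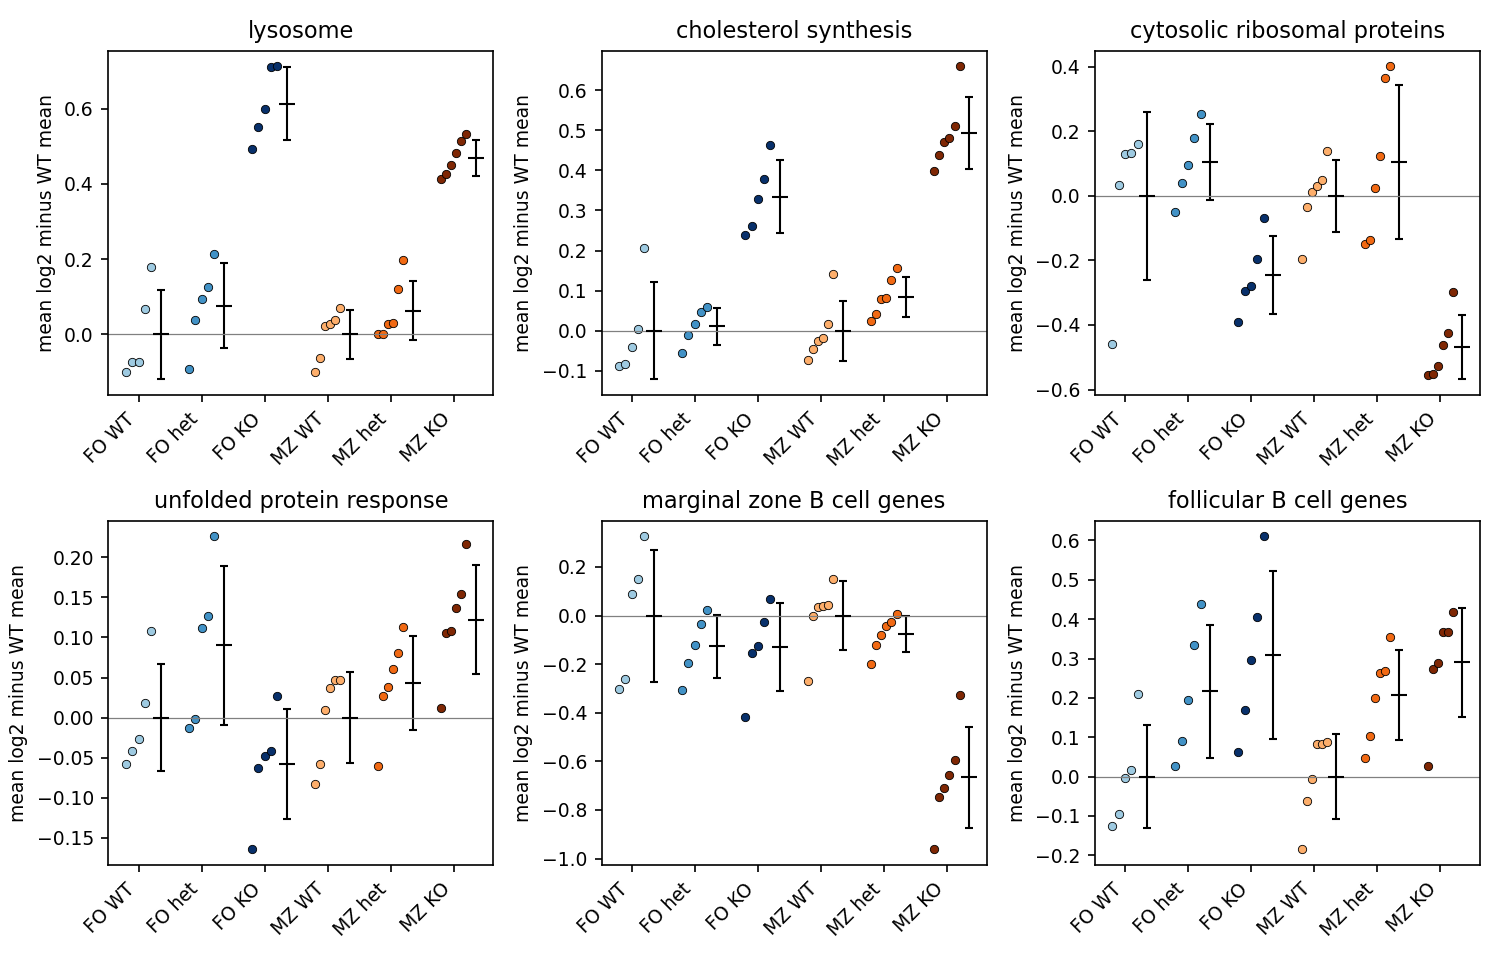
Mean log2 value of 6 gene lists per library minus the WT mean of the same cell type, for WT, het and KO of FO and MZ cells. Points are libraries and bars are mean ± SD; lysosomal genes sit at 0.493 to 0.713 in FO KO and 0.412 to 0.532 in MZ KO, above every WT library (0.179 at most), while under median scaling the ribosomal protein mean turns from -0.25 to 0.10 in FO KO and from -0.47 to 0.12 in MZ KO (-0.26 and -0.47 under quantile normalization), and the MZ gene mean from -0.13 to 0.21 in FO KO, but stays negative in MZ KO (-0.67 to -0.07, and -0.63 under quantile normalization).

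Compared with FO het cells, whose background was closer to that of FO KO, lysosomal genes were again higher in FO KO. Hexa rose from 92.5 ± 12.1 to 289.9 ± 29.2 TPM, log2 1.63 ± 0.08, adjusted p = 9.97e-17, Gns from 68.7 to 180.4 TPM, Lamp2, a lysosomal membrane protein, from 42.5 to 78.2 TPM, and of lysosomal genes 23 of 40 rose and 0 fell, 29 and 1 adjusted over the list alone. Across the list, median log2 change was 0.48 (adjusted p = 3.82e-49, or adjusted p = 1.43e-05 with an estimated correlation). Fam167a (8.34 ± 1.29 to 49.1 ± 2.69 TPM, log2 2.55 ± 0.14, adjusted p = 1.37e-15) and Fbxw13, an F-box protein (log2 3.75 ± 0.55, adjusted p = 1.71e-05), rose most among genes named by rank, with Fam221a (log2 3.00 ± 0.76, adjusted p = 0.0154), whose call was lost without FO het 1 (2.39, adjusted p 0.0763). Asb2 fell from 12.5 ± 7 to 2.46 ± 0.888 TPM, log2 -2.24 ± 0.32, adjusted p = 1.56e-05 and Mef2b, a germinal centre factor, from 13.7 to 3.66 TPM (log2 -1.93 ± 0.41, adjusted p = 0.00259). Kel fell too (log2 -2.05 ± 0.58, adjusted p = 0.0357), but not without FO het 1, 3, 4 or 6 or FO KO 3, 4 or 6 (adjusted p 0.0538 to 0.106). Of mTORC1 pathway components, 4 of 31 rose and 0 fell, 4 and 0 adjusted over the list alone. By median, log2 change was 0.04 (adjusted p = 0.000161, or adjusted p = 0.00133 with an estimated correlation). Flcn went from 43.1 to 104 TPM. Of cholesterol synthesis genes, 7 of 24 rose and 0 fell, 9 and 0 adjusted over the list alone. For the list, median log2 change was 0.31 (adjusted p = 1.82e-09, or adjusted p = 0.00177 with an estimated correlation). Of germinal centre B cell genes, 0 of 10 rose and 4 fell, 0 and 5 adjusted over the list alone. In log2, the median change was -0.91 (adjusted p = 5.02e-05, or adjusted p = 0.0387 with an estimated correlation). Cxcr3, a chemokine receptor, fell from 6.77 to 1.98 TPM. Of cytosolic ribosomal protein genes, 0 of 80 rose and 40 fell, 0 and 68 adjusted over the list alone. The median log2 change was -0.36 (adjusted p = 2.05e-39, or adjusted p = 0.169 with an estimated correlation). Ifi27l2a, an interferon-inducible gene, rose from 523 to 1076 TPM. In total 471 genes rose and 360 fell, against 68 and 6 under median scaling, with 653 to 861 genes when 1 library was left out. Groups did not overlap for 431 higher and 376 lower genes, 3.93% where chance gives 0.794%.

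In MZ cells, loss of both Tsc1 alleles again went with higher Apoe and lysosomal genes, and with lower Cd1d1 and Asb2. Apoe rose 5.87-fold from 274 ± 59.6 to 1664 ± 187 TPM, log2 2.55 ± 0.14, adjusted p = 3.69e-15. Hexb, the partner subunit of Hexa (chromosome 13, 97176331 to 97198357, minus strand), rose from 40.9 ± 4.32 to 103 ± 15.7 TPM, log2 1.25 ± 0.11, adjusted p = 2.88e-10, and of lysosomal genes 25 of 40 rose and 0 fell, 26 and 0 adjusted over the list alone. Their median log2 change was 0.49 (adjusted p = 7.57e-33, or adjusted p = 0.000120 with an estimated correlation). Cd1d1 (chromosome 3, 86995834 to 86999441, minus strand) fell from 478 ± 61.0 to 175 ± 46.3 TPM, log2 -1.55 ± 0.16, adjusted p = 6.47e-09, and Asb2 (chromosome 12, 103321142 to 103356001, minus strand) from 83.8 ± 14.02 to 18.7 ± 6.59 TPM, log2 -2.29 ± 0.29, adjusted p = 9.52e-07. Crisp3 (chromosome 17, 40221777 to 40242288, minus strand), a gene that MZ WT cells expressed less than FO WT cells, rose from 1.36 ± 0.907 to 22.4 ± 8.24 TPM, log2 4.12 ± 0.34, adjusted p = 4.97e-11.

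Other large rises were Myadm (6.79 ± 2.00 to 43.3 ± 13.3 TPM, log2 2.58 ± 0.22, adjusted p = 4.65e-10), Vim, an intermediate filament (log2 2.41 ± 0.21, adjusted p = 8.50e-10), S100a6, a calcium-binding protein (log2 2.45 ± 0.40, adjusted p = 4.75e-05), Fbxw13 (log2 2.58 ± 0.50, adjusted p = 0.000495), Coprs (log2 3.38 ± 0.83, adjusted p = 0.00483) and Fam221a (log2 2.86 ± 0.69, adjusted p = 0.00450). Large falls were Klf2 (262 ± 129 to 52.3 ± 14.8 TPM, log2 -2.30 ± 0.40, adjusted p = 0.000222), Rap1gap (log2 -2.30 ± 0.34, adjusted p = 9.03e-06), Stc1, a secreted glycoprotein (log2 -3.43 ± 0.71, adjusted p = 0.000993), Adam28, a metalloprotease (log2 -2.28 ± 0.37, adjusted p = 3.92e-05), Jund, an AP-1 factor (log2 -2.23 ± 0.55, adjusted p = 0.00593), and Yrdc (log2 -2.28 ± 0.65, adjusted p = 0.0146). Klf2, Jund and Yrdc belong to the same block of 16 genes that varied together between libraries. Klrb1f was named by rank too, but its adjusted p of 0.0493 was close to 0.05. It was 0.0502 to 0.129 without any 1 of 24 libraries, namely FO WT 1, 3, 4, 5 or 6, FO het 1, 2 or 3, FO KO 2, 3 or 4, MZ WT 2, 3, 4, 5 or 6, MZ het 1, 2, 3, 4 or 6, or MZ KO 1, 2 or 4.

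Among MZ B cell genes 1 of 17 rose and 8 fell, 1 and 10 adjusted over the list alone, at a median log2 change of -0.53, 0.07 under median scaling and -0.56 under quantile normalization (adjusted p = 0.000204, or adjusted p = 0.0546 with an estimated correlation). Dtx1 fell from 558 to 362 TPM and Tlr3, a sensor of double-stranded RNA, from 10.2 to 2.99 TPM. Of FO B cell genes, 7 of 10 rose and 2 fell, 8 and 2 adjusted over the list alone. The list had a median log2 change of 0.46 (adjusted p = 9.57e-07, or adjusted p = 0.0139 with an estimated correlation). Itgb7 rose from 35.9 ± 7.06 to 124 ± 34.1 TPM, log2 1.69 ± 0.15, adjusted p = 2.31e-10, Cd55 from 91.7 to 156 TPM and Bach2, a repressor of plasma cell fate, from 11.9 to 22.6 TPM, while Klf2 fell. Of Notch targets, 0 of 10 rose and 5 fell, 0 and 6 adjusted over the list alone. These genes had a median log2 change of -0.74 (adjusted p = 0.0381, or adjusted p = 0.174 with an estimated correlation). The list's preset p was 0.159 without MZ WT 1, 0.0693 without MZ WT 4, 0.0692 without MZ KO 4 and 0.0511 without MZ KO 6. Hes5 went from 17.1 to 6.34 TPM and Myc from 1077 to 658 TPM. Of migration receptors, 9 of 25 rose and 5 fell, 10 and 5 adjusted over the list alone. At the median, log2 change was 0.18 (adjusted p = 1.67e-06, or adjusted p = 0.00570 with an estimated correlation). S1pr4, a sphingosine phosphate receptor, rose from 16.7 to 41.6 TPM, Cxcr4, the CXCL12 receptor, from 55.6 to 107 TPM and Rgs1, which damps chemokine signals, from 23.8 to 57.7 TPM.

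Of mTORC1 pathway components, 10 of 31 rose and 0 fell, 11 and 0 adjusted over the list alone. As a list they had a median log2 change of 0.22 (adjusted p = 7.66e-09, or adjusted p = 7.37e-06 with an estimated correlation). Flcn went from 49.8 to 103 TPM, Lamtor1 from 73.2 to 125 TPM and Rragd from 2.96 to 7.50 TPM. Of cholesterol synthesis genes, 14 of 24 rose and 0 fell, 15 and 1 adjusted over the list alone. List members had a median log2 change of 0.40 (adjusted p = 2.07e-15, or adjusted p = 8.77e-05 with an estimated correlation). Ldlr (chromosome 9, 21723483 to 21749919, plus strand) went from 1.56 ± 0.359 to 7.20 ± 1.10 TPM, log2 2.14 ± 0.18, adjusted p = 4.97e-11 and Hmgcs1 from 13.1 to 22.5 TPM. Of cytosolic aminoacyl-tRNA synthetases, 7 of 20 rose and 0 fell, 9 and 0 adjusted over the list alone. Its median log2 change was 0.24 (adjusted p = 9.95e-09, or adjusted p = 0.00570 with an estimated correlation). Of unfolded protein response genes, 11 of 36 rose and 2 fell, 12 and 3 adjusted over the list alone. Median log2 change was 0.19 (adjusted p = 3.39e-08, or adjusted p = 0.0394 with an estimated correlation). Of secretory translocation genes, 9 of 45 rose and 1 fell, 10 and 1 adjusted over the list alone. Across the list, median log2 change was 0.13 (adjusted p = 4.64e-08, or adjusted p = 0.0409 with an estimated correlation). Of proteasome genes, 14 of 40 rose and 0 fell, 15 and 0 adjusted over the list alone. By median, log2 change was 0.17 (adjusted p = 2.59e-12, or adjusted p = 0.0280 with an estimated correlation). Of these last 4 lists, all but proteasome genes passed with both correlations in MZ het against MZ WT too, and none passed with an estimated correlation in MZ KO against MZ het. Herpud1, which acts in degradation from the endoplasmic reticulum, rose from 118 to 186 TPM, and the disulfide isomerase Txndc5 from 70.2 to 116 TPM. Of ATF4 targets, 7 of 25 rose and 1 fell, 7 and 2 adjusted over the list alone. For the list, median log2 change was 0.17 (adjusted p = 6.47e-05, or adjusted p = 0.0756 with an estimated correlation). Trib3 went from 0.498 to 3.44 TPM and Ddit3 from 71.6 to 130.2 TPM. Pik3ip1 rose from 59.0 to 231 TPM, Pdcd1lg2 from 10.5 to 29.9 TPM, Ahnak from 2.43 to 10.9 TPM and Btk, the B cell receptor kinase, from 109 to 166 TPM. Of MHC class II genes, 5 of 11 rose and 0 fell, 5 and 0 adjusted over the list alone. In log2, the median change was 0.09 (adjusted p = 0.000108, or adjusted p = 0.215 with an estimated correlation). Ciita, the class II transactivator, went from 99.3 to 163 TPM and H2-DMb1 from 193 to 294 TPM. Of cytosolic ribosomal protein genes, 0 of 80 rose and 75 fell, 0 and 76 adjusted over the list alone, at a median log2 change of -0.48, 0.11 under median scaling and -0.51 under quantile normalization (adjusted p = 1.40e-25, or adjusted p = 0.179 with an estimated correlation). Rps19 fell from 6685 to 4406 TPM.

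In total 1329 genes rose and 3306 fell in MZ KO, with 146 and 2570 by at least 2-fold. The lower genes had a median mean of 1.96 TPM against 53.2 TPM for the higher ones. The split was 4382 and 1484 under median scaling, 1289 and 924 under quantile normalization, 1148 and 653 among genes with a mean of at least 20 TPM, and 648 and 620 with a background term. Leaving out MZ WT 1 gave 7722 genes, MZ WT 2 gave 2780.0, MZ WT 6 gave 2662 and MZ KO 5 gave 2948, and leaving out MZ WT 1 and FO KO 6 together gave 8360.0. Groups did not overlap for 746 higher and 684 lower genes, 6.97% where chance gives 0.216%.

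**Figure D3:**
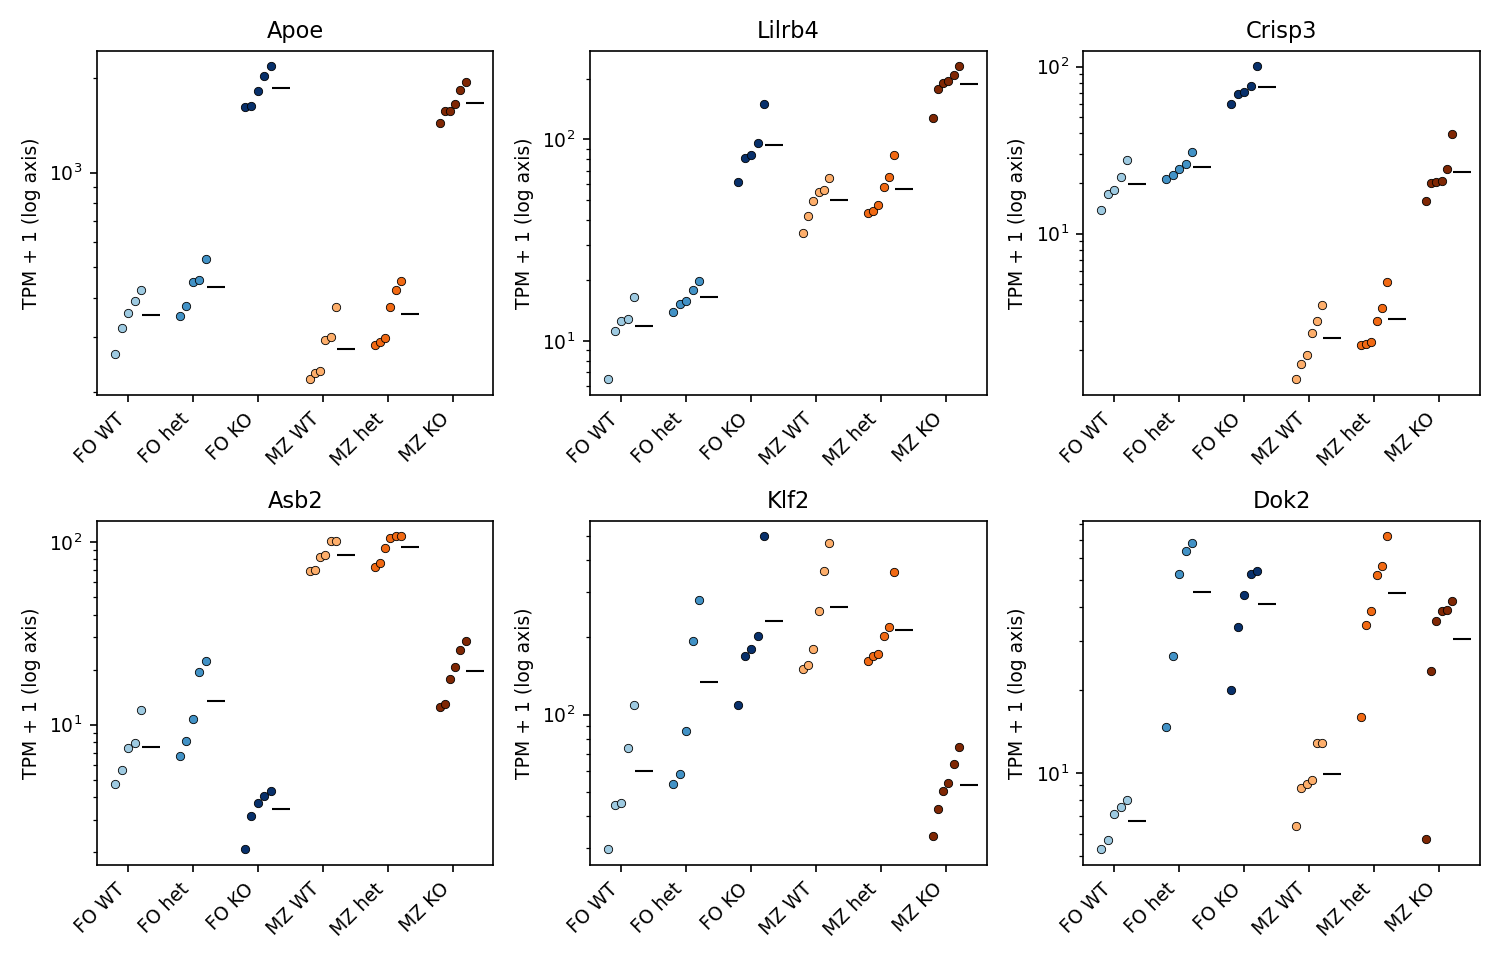
TPM + 1 per library on a log axis for Apoe, Lilrb4, Crisp3, Asb2, Klf2 and Dok2 in the 6 groups. Points are libraries and bars are means; Apoe averages 349.9 and 1851 TPM in FO WT and FO KO, and 274 and 1664.5 TPM in MZ WT and MZ KO.

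MZ KO and MZ het libraries had similar background. Between them 6 lists passed with both correlations, where 10 did between MZ KO and MZ WT, and only lysosomal genes, cholesterol synthesis and mTORC1 pathway components were in both sets. MZ het against MZ WT passed 17, among them 9 of those 10 (all but proteasome genes), at list medians of -0.06 to 0.21 where that of all genes was -0.30. Ribosomal protein genes were lower together in MZ KO, and of these genes 0 of 80 rose and 76 fell, 0 and 76 adjusted over the list alone. The median log2 change was -0.61 (adjusted p = 3.21e-87, or adjusted p = 0.0125 with an estimated correlation). Rpsa went from 1409.8 ± 116 to 799 ± 47.3 TPM, log2 -0.89 ± 0.09, adjusted p = 2.72e-09 and Rpl12 from 541 to 294 TPM. Of lysosomal genes, 24 of 40 rose and 0 fell, 28 and 0 adjusted over the list alone. Their median log2 change was 0.38 (adjusted p = 1.42e-25, or adjusted p = 0.00122 with an estimated correlation). Hexa went from 117 to 241 TPM and Atp6v0a1, a proton pump subunit, from 18.4 to 57.2 TPM. Of MZ B cell genes, 1 of 17 rose and 9 fell, 1 and 10 adjusted over the list alone. The list had a median log2 change of -0.57 (adjusted p = 1.57e-09, or adjusted p = 0.00306 with an estimated correlation). Cd1d1 fell from 400.4 ± 52.0 to 175 ± 46.3 TPM, log2 -1.30 ± 0.16, adjusted p = 2.85e-07, Asb2 from 92.5 to 18.7 TPM and Notch2, the receptor that MZ cells depend on, from 51.3 to 34.9 TPM (log2 -0.63 ± 0.09, adjusted p = 4.59e-06). Among Notch targets 0 of 10 rose and 5 fell, 0 and 7 adjusted over the list alone. These genes had a median log2 change of -0.87 (adjusted p = 7.36e-06, or adjusted p = 0.00338 with an estimated correlation). Myc went from 1281 to 658 TPM and Dtx1 from 542 to 362 TPM. Of cholesterol synthesis genes, 11 of 24 rose and 0 fell, 14 and 0 adjusted over the list alone. At the median, log2 change was 0.42 (adjusted p = 1.09e-10, or adjusted p = 0.00122 with an estimated correlation). Of mTORC1 pathway components, 6 of 31 rose and 1 fell, 7 and 1 adjusted over the list alone. As a list they had a median log2 change of 0.13 (adjusted p = 0.000398, or adjusted p = 0.00156 with an estimated correlation). Crisp3 (log2 3.42 ± 0.34, adjusted p = 5.88e-09), Fbxw13 (log2 3.23 ± 0.50, adjusted p = 2.35e-05) and S100a6 (log2 2.74 ± 0.40, adjusted p = 8.69e-06) rose most among genes named by rank, while Fam149a (log2 -3.27 ± 0.51, adjusted p = 2.61e-05) and Tmem121 (log2 -2.37 ± 0.52, adjusted p = 0.00187) fell most beside Asb2. Nr4a1, an immediate early nuclear receptor, fell from 995 to 602 TPM. Of interferon-stimulated genes, 5 of 26 rose and 0 fell, 7 and 0 adjusted over the list alone. List members had a median log2 change of 0.42 (adjusted p = 4.95e-06, or adjusted p = 0.323 with an estimated correlation). Ifit2 went from 5.66 to 13.6 TPM. In total 959 genes rose and 602 fell, 123 and 81 under median scaling, with 1304 to 1631 genes when 1 library was left out. Groups did not overlap for 654 higher and 507 lower genes, 5.66% where chance gives 0.216%.

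The difference between the KO effects of MZ and FO cells asked which responses depended on cell type. Cd55 rose in MZ KO and differed by 0.89 ± 0.13 between cell types (adjusted p = 0.000163), and Dtx1, which rose in FO KO and fell in MZ KO, differed by -1.39 ± 0.16 (adjusted p = 2.19e-06). Klf2 (chromosome 8, 72319033 to 72321656, plus strand) differed by -4.21 ± 0.60 (adjusted p = 0.000178), Jund by -4.65 ± 0.81 (adjusted p = 0.00189) and Hes1 by -2.35 ± 0.49 (adjusted p = 0.00739), all members of the block of 16 genes. S1pr1, higher in FO KO, differed by -0.88 ± 0.14 (adjusted p = 0.000311) and Nfil3, a circadian and immune factor, by -3.68 ± 0.61 (adjusted p = 0.000582). Crisp3 (2.11 ± 0.50), Vpreb3, a surrogate light chain gene (1.88 ± 0.40), Gadd45g, a stress-response gene (1.67 ± 0.28), and Zbtb32, a repressor in activated B cells (2.64 ± 0.62), had positive differences, as did Ldlr (1.37 ± 0.26) and H2-Ob, an MHC class II chaperone (0.73 ± 0.11). Hexa rose less in MZ than in FO cells (-0.59 ± 0.11, adjusted p = 0.00200). As a list, lysosomal genes did not pass the test of the difference, and 1 of 40 rose and 3 fell, 1 and 4 adjusted over the list alone, at a median log2 change of -0.14, 0.10 under median scaling and -0.17 under quantile normalization (adjusted p = 0.0713, or adjusted p = 0.619 with an estimated correlation). Of Notch targets, 0 of 10 rose and 2 fell, 0 and 4 adjusted over the list alone. Its median log2 change was -1.16 (adjusted p = 0.000169, or adjusted p = 0.0641 with an estimated correlation). Of cell cycle genes, 2 of 36 rose and 0 fell, 14 and 0 adjusted over the list alone. Median log2 change was 0.69 (adjusted p = 1.23e-12, or adjusted p = 0.242 with an estimated correlation). No list of the 40 passed with an estimated correlation. In total 191 differences were positive and 205 negative, 0 and 0 under median scaling. KO with WT shared 435 higher genes between the cell types where independent lists would share 44.7, and 159 lower genes where they would share 94.3. Of these, 26 and 1 passed the test of the difference. Another 38 rose in FO and fell in MZ, and 11 fell in FO and rose in MZ. Across genes, which are not independent replicates, the KO effects correlated at r = 0.439, and at 0.513 over 5863 genes with a mean of at least 20 TPM.

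Few genes were called between FO het and FO WT. Ier2, an immediate early gene, rose from 230.1 ± 25.6 to 354 ± 40.5 TPM, log2 0.64 ± 0.10, adjusted p = 0.00567. Dok2 (chromosome 14, 70766036 to 70778495, plus strand) rose from 5.71 ± 1.17 to 44.1 ± 23.4 TPM, log2 2.75 ± 0.47, adjusted p = 0.0254, and Plaur, the urokinase receptor, from 191 ± 37.8 to 328 ± 59.3 TPM, log2 0.81 ± 0.15, adjusted p = 0.0336. Hs3st1, a heparan sulfate sulfotransferase, was the other called gene, chosen after its values were seen, and went from 85.1 to 144 TPM (log2 0.78 ± 0.14, adjusted p = 0.0254). These 4 rose and 0 fell by limma, with 1608 at an unadjusted p under 0.05, and the split was 0 and 0 under median scaling and 23 and 7 under quantile normalization. Dok2 lost its call without FO WT 1, FO WT 6, FO het 2, FO het 4 or FO het 6 (adjusted p 0.0605 to 0.125), and Plaur without FO WT 1, FO WT 3, FO WT 6, FO het 1, FO het 2 or FO het 4 (0.0643 to 0.164). The count was 2 without FO WT 1, 7 without FO WT 4, 24 without FO WT 5, 1 without FO WT 6, 2 without FO het 2, 14 without FO het 3, 2 without FO het 4 and 8 without MZ WT 5. Groups did not overlap for 90 higher and 152 lower genes, 1.18% where chance gives 0.794%. Of immediate early genes, 1 of 25 rose and 0 fell, 6 and 0 adjusted over the list alone. Across the list, median log2 change was 0.36 (adjusted p = 2.23e-14, or adjusted p = 0.0273 with an estimated correlation). Of migration receptors, 0 of 25 rose and 0 fell, 2 and 0 adjusted over the list alone. By median, log2 change was 0.14 (adjusted p = 4.08e-07, or adjusted p = 0.0159 with an estimated correlation). Of myeloid markers, 0 of 18 rose and 0 fell, 8 and 0 adjusted over the list alone. For the list, median log2 change was 0.62 (adjusted p = 5.16e-08, or adjusted p = 0.0881 with an estimated correlation).

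In MZ het cells, Dok2 again rose (8.89 ± 2.52 to 43.9 ± 19.6 TPM, log2 2.20 ± 0.43, adjusted p = 0.0133), as did Supt16, a histone chaperone subunit (18.3 ± 1.56 to 44.1 ± 11.2 TPM, log2 1.24 ± 0.25, adjusted p = 0.0141). Ccr6, a chemokine receptor, rose from 46.9 ± 10.1 to 78.4 ± 13.9 TPM, log2 0.76 ± 0.12, adjusted p = 0.00374, Itgb7 from 35.9 to 64.5 TPM, Gpr183, which guides B cells within follicles, from 129 to 205 TPM, Ier2 from 127 to 179 TPM and Sesn1, a stress-induced mTORC1 inhibitor, from 120.4 to 187 TPM. Ypel1 fell from 15.8 ± 3.37 to 5.12 ± 1.33 TPM, log2 -1.61 ± 0.30, adjusted p = 0.00523. AF067061 (log2 -1.85 ± 0.48, adjusted p = 0.0408) and Tbc1d13 (log2 -1.59 ± 0.39, adjusted p = 0.0338) were also named by rank. AF067061 lost its call without MZ WT 2, 3, 4, 5 or 6 or MZ het 1, 2, 4 or 5 (adjusted p 0.0555 to 0.112), and Tbc1d13 without MZ WT 2, 3, 4 or 5 or MZ het 2, 4 or 5 (0.0564 to 0.105). Here 32 of 40 lists passed the preset test (median of all genes -0.30). Of migration receptors, 4 of 25 rose and 0 fell, 7 and 0 adjusted over the list alone. In log2, the median change was 0.15 (adjusted p = 1.50e-11, or adjusted p = 0.000557 with an estimated correlation). Of MHC class II genes, 2 of 11 rose and 0 fell, 11 and 0 adjusted over the list alone. The median log2 change was 0.21 (adjusted p = 1.88e-13, or adjusted p = 0.0296 with an estimated correlation). Of FO B cell genes, 1 of 10 rose and 0 fell, 3 and 0 adjusted over the list alone. Their median log2 change was 0.21 (adjusted p = 2.57e-07, or adjusted p = 0.0221 with an estimated correlation). Of immediate early genes, 4 of 25 rose and 0 fell, 7 and 0 adjusted over the list alone. The list had a median log2 change of 0.25 (adjusted p = 2.53e-10, or adjusted p = 0.0296 with an estimated correlation). Of interferon-stimulated genes, 0 of 26 rose and 10 fell, 0 and 15 adjusted over the list alone. These genes had a median log2 change of -0.69 (adjusted p = 6.41e-06, or adjusted p = 0.192 with an estimated correlation). In total 87 genes rose and 591 fell, 2102 and 506 under median scaling and 58 and 21 under quantile normalization, and the lower genes had a median mean of 2.26 TPM. With a background term 3 rose and 1 fell. Groups did not overlap for 90 higher and 242 lower genes, 1.62% where chance gives 0.216%. Leaving out MZ WT 1 to 6 in turn gave 4464, 42, 76, 64, 146 and 77 genes, and leaving out MZ het 1 to 6 gave 328, 77, 227, 151, 205 and 426. It gave 420.0 without MZ KO 2 and 398, 385, 373 and 386 without FO WT 1, 3, 4 and 6. It gave 414, 369 and 383 without FO het 1, 2 and 6 and 437, 401 and 1704 without FO KO 4, 5 and 6.

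A final set of comparisons asked whether deletion moved FO cells toward the MZ profile. Across 20513 genes, log2 FO KO minus FO het correlated with MZ WT minus FO WT at r = 0.115 (jackknife SE 0.372), and at 0.121 over the 3890 genes called between the WT groups. Leaving out 1 library moved r from -0.176 without FO KO 6 to 0.243 without FO het 4. FO KO minus FO WT, which shares the FO WT libraries, gave r = 0.502 where simulation of shared controls alone gave 0.521, with covariances of 0.304 and 0.188, and 0.210 with split controls. The score of MZ-like expression was 1.22 ± 0.244 in FO WT, 1.66 ± 0.297 in FO het, 1.73 ± 0.526 in FO KO and 3.46 ± 0.565 in MZ WT. The difference of FO KO from FO het was 0.0714 (exact permutation p = 0.794, two-sided, adjusted p = 0.794 over 8 tests), where the smallest possible p was 0.00794. From FO WT, whose libraries also chose the genes of the score, it was 0.506 (exact permutation p = 0.0556, adjusted p = 0.111). The FO KO difference from het was -0.00129 without FO het 3 and -0.198 without FO KO 6.

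Immunoglobulin transcripts were read from the table that holds them. In MZ KO they took 4.80 ± 0.260% of TPM against 3.99 ± 0.235% in MZ WT (exact permutation p = 0.00433, adjusted p = 0.0303 over 7 comparisons, two-sided). The share was 4.36% in MZ WT 1, the MZ WT library of lowest background, and 3.66% to 4.06% in the others. MZ KO libraries, all of low background, ran from 4.32% to 5.04%. Background and deletion thus cannot be told apart for this difference. In FO KO the share was 4.47 ± 0.181% against 4.56 ± 0.427% in FO WT (exact permutation p = 0.683). MZ WT had a lower share than FO WT by 0.569 points of percent, a difference of -0.569 (exact permutation p = 0.0108, adjusted p = 0.0379). MZ het stood at 4.48 ± 0.382% (exact permutation p = 0.0281 against MZ WT, adjusted p = 0.0657) and FO het at 4.93 ± 0.532% (exact permutation p = 0.246 against FO WT). KO compared with het gave an exact permutation p of 0.127 in FO and 0.123 in MZ. Leaving out FO het 1 brought the former to 0.0238 and MZ KO 3 the latter to 0.0390, and leaving out MZ WT 6 or MZ het 1 brought MZ het against MZ WT to 0.0563 or 0.0519. Ighd, the IgD heavy chain, rose in MZ KO from 421 ± 52.2 to 1042 ± 229.9 TPM (log2 1.23 ± 0.11, adjusted p = 1.18e-09). It was 2261 ± 139 TPM in FO WT and 2158 ± 244 TPM in FO KO, and the KO effects differed by 1.2999 ± 0.17 (adjusted p = 2.98e-05). Ighm, the IgM heavy chain, rose in MZ KO from 5361.5 ± 331 to 6435 ± 595 TPM (log2 0.20 ± 0.07, adjusted p = 0.0402).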

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

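The tests of KO with het on the surplus of lower genes, of the correlation within het libraries, of gene length and of FO KO with het on the block of genes were chosen only after the result was seen, and the model with a background term was added after seeing the data.

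More genes fell than rose in MZ KO compared with MZ WT, at 71.3% of called genes, and the lower genes were weakly expressed. With background as a model term the share was 48.9%, as higher background in MZ WT would give. Loss of the second Tsc1 allele as the source is argued against by MZ KO with MZ het (38.6% lower). Loss of 1 allele stays open, since 87.2% were lower in MZ het with MZ WT, where the term cannot part it from background. Without MZ WT 1, lowest of all 33 in background (0.0383 TPM), 7722 genes were called. In each group but MZ het, the library of most reads had least background. What raised it stays open, as labels give no batch.

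A block of 16 genes, Chic2, Coq2, Grb2, Hes1, Jund, Klf2, Lamp1, Nsmce4a, Pnrc1, Rnf187, Rnf220, Smarcd2, Taf10, Tmem165, Yrdc and Zfand5, was chosen for a KO effect at least 2 log2 units lower in MZ than in FO cells, so its opposite median log2 changes of 1.57 in FO KO and -1.38 in MZ KO against WT follow from the choice. Within the het libraries alone, deviations of these genes from group means had a median pairwise correlation of 0.877, where 200 random sets reached 0.240 at most, so a factor of single libraries that moves them together may contribute. Their median length lay at percentile 4.01 of matched random sets (2089 against 2913.5 bases) and their GC content at percentile 85.6 (51.8% against 49.4%), which leaves gene length open. Loss of both Tsc1 alleles stays open too: the median was 0.478 in FO KO against FO het, 0.99 in FO het against FO WT and -1.46 in MZ KO against MZ het, and each shares libraries with the choice of the genes. Sample handling was not recorded in the labels and no test of it could be made.

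In FO KO, 15 of 36 cell cycle genes fell (adjusted p = 0.147 for the list with an estimated correlation), as did the erythroid genes Gfi1b, Kel, Epor and Rhd, although the first 3 of these lost their calls without single libraries, named above. Over the 15 FO libraries their deviations from group means correlated at r = 0.894 (Spearman rho 0.918, permutation p = 3.00e-05 each, two-sided, 1 relation tested), 0.853 without the 2 farthest libraries and 0.910 given the background, which is in line with fewer dividing erythroid precursors. Car1 averaged 91.5 ± 37.8 TPM in FO WT and 33.6 ± 19.5 in FO KO, Car2 183 ± 85.4 and 85.4 ± 16.7, and Klf1 23.4 ± 12.0 and 7.77 ± 2.85, none past the test. Haemoglobin was not lower, with Hbb-bs at 1021 ± 959 and 1242 ± 453 TPM and Hba-a1 at 823 ± 712 and 995 ± 367. The sort on CD19 would remove erythroid cells, and cycling B cells or a change in RNA from other cells stays open.

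Other splits of the same libraries, up to 100 each, tested whether chance can explain the counts of called genes. Chance can be excluded for KO with WT in FO (1275 genes, at most 854 in another split) and MZ (4635, at most 1198), for KO with het in FO (831, 292) and MZ (1561, 472), for het with WT in MZ (678, 19) and for the difference of KO effects (396, 2). It is not clearly excluded for MZ with FO WT (3890.0 genes), where 2 of 100 splits, the real one counted, called as many. The other split called 4191, and how it grouped the libraries was not examined. Chance cannot be excluded for het with WT in FO (4 genes), where 5 of 100 splits, the real one counted, called as many. Of these 1 called 161, pointing to untested structure of the samples.

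Dixon's test for a library far from its group marks about 1 in 20 groups by chance. It marked 3 of 78 group means of library measures, where chance gives 3.9. These were the mean log2 of ribosomal protein genes in FO WT 1 (8.05, the next library 8.54), of MZ genes in MZ WT 6 (7.34, next 7.61) and of FO genes in MZ KO 1 (7.66, next 7.91). It marked 30 of 366 groups of named genes, where chance gives 18.3, and the values that follow are TPM. Dok2 was 4.78 in MZ KO 1 (next 22.3) and Supt16 was 16.0 there (next 46.9). Klf2 was 359 in MZ het 5 (next 202), and Yrdc was 73.5 in that library and 101 in FO KO 6. Tsc1 was 21.8 in MZ het 1, Vim 61.7 in MZ WT 6, Fam167a 33.7 in MZ KO 2, Hspa1a 38.5 in FO KO 5, Wfdc17 104.8 in FO KO 3 and Ackr2 36.2 in MZ het 3. Gfi1b was 2.49 in MZ WT 1 and 22.3 in MZ het 1, and Pde2a was 1.93 in FO het 3 and 0 in MZ WT 5. AF067061 was 1.43 in FO WT 5 and 4.55 in FO het 2, Ypel1 9.45 in FO WT 5, Kif22 1.54 in FO KO 3 and Tbc1d13 1.95 in FO KO 6. Fam149a was 1.73 in MZ WT 3, Flt3l 2.21 in MZ WT 2, Mef2b 5.57 in MZ WT 1, Mapk12 0.267 in MZ het 6 and Vwa5a 17.5 in MZ KO 6. Klrb1f was 2.36 in FO het 6, 4.77 in FO KO 5 and 0 in MZ het 5, and RP23-370F14.2 was 5.92 in MZ het 6 and 11.2 in MZ KO 3.

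The KO effect differed between MZ and FO cells by the test of the difference itself for 11 single genes listed here, in log2 units of MZ minus FO. The difference was 2.74 for Gml, 2.64 for Zbtb32, 2.11 for Crisp3, 1.88 for Vpreb3, 1.67 for Gadd45g and 1.2999 for Ighd. It was -4.65 for Jund, -4.21 for Klf2, -3.94 for Yrdc, -3.68 for Nfil3 and -3.55 for Flt3l. Yrdc lost its call without FO WT 1 (adjusted p 0.0539). Gml lost it without FO WT 1, 3 or 4, FO KO 3 or 6, MZ WT 4, 5 or 6, MZ het 1, 2, 4, 5 or 6, or MZ KO 1, 3, 4 or 5 (0.0503 to 0.0936). Flt3l lost it without FO WT 3, 5 or 6, FO KO 4, MZ WT 4 or 5, or MZ KO 1 or 2 (0.0541 to 0.0756).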

How the results depend on the processing

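Alternatives not named above as chosen after seeing the data were chosen before. Of 704 results of a named gene in a comparison, 623 kept their direction and call with a pseudocount of 1, 614 with 5 and 645 with 0.1, 321 under median scaling, 617 under quantile normalization, 658 without a filter, 598 with weights from TPM, 675 with weights per library, 620 without trend or robust moderation, 565 with only the compared groups in the model, 652 and 703 with the replicate blocks, 598 with a background term, 661 with a sex term and 704 in the table with immunoglobulin genes. Of 171 list calls, 54 held with an estimated correlation, 140 under median scaling, 130 under quantile normalization, 111 at 5 TPM, 74 at 20 TPM and 124 with a background term. FO and MZ libraries of 1 genotype and number were alike in sex in 15 of 15 pairs, correlated above 0.1 in 11 (median 0.159) and best with their own number in 8. The rule for pairing asked for a correlation above 0.1 in every pair, so the blocks are a hint from the data, and whether a number marks 1 animal stays open. Except where fewer genes or libraries were tested, the cause was not tested.

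Called genes of KO with WT in FO, KO with WT in MZ, het with WT in FO, het with WT in MZ, MZ with FO WT, KO with het in FO, KO with het in MZ and the difference are named here as FO KO, MZ KO, FO het, MZ het, MZ WT, FO KO-het, MZ KO-het and the difference. A 2-fold minimum gave 267, 2716 and 1 genes for FO KO, MZ KO and FO het, 1673 for MZ WT, 135 for FO KO-het, 313 for MZ KO-het and 197 for the difference. A pseudocount of 1 gave 53 for FO het and 39 for MZ het, a pseudocount of 0.1 gave 10 for FO het, and a pseudocount of 5 gave 2639 for MZ KO, 93 for FO het, 28 for MZ het and 5962 for MZ WT. Median scaling gave 246 for FO KO, 0 for FO het, 2608 for MZ het, 74 for FO KO-het, 204 for MZ KO-het and 0 for the difference, and quantile normalization 2213 for MZ KO, 30 for FO het and 79 for MZ het. No filter gave 412 for MZ het, and a mean of at least 5 TPM gave 2515 for MZ KO, 15 for FO het and 148 for MZ het. Weights from TPM gave 2454 for MZ KO, 47 for FO het and 18 for MZ het. Weights per library gave 8439 for MZ KO, 21 for FO het, 5315 for MZ het and 934 for the difference. Without trend or robust moderation there were 2 for FO het, 364 for MZ het and 257 for the difference. With only the compared groups there were 527 for FO KO, 313 for MZ het and 395 for FO KO-het, and the replicate block across groups gave 17 for FO het and 316 for MZ het.

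A mean of at least 20 TPM gave 1801 for MZ KO, 24 for FO het, 88 for MZ het and 2206 for MZ WT. The background term gave 1268 for MZ KO, 4 for MZ het and 2220.0 for MZ WT, and 1164 of the 1268 were called without it. The sex term gave 9 for FO het and 149 for MZ het, and weights from estimated counts 1 and 118. Leaving out MZ WT 1 and FO KO 6 gave 8360.0 for MZ KO, 12 for FO het, 5313 for MZ het and 2357 for the difference. The MZ score difference of FO KO and FO het was -0.0186 at 20 TPM (exact permutation p = 0.770), -0.0564 with the background term (0.413) and -0.125 without MZ WT 1 and FO KO 6 (0.317).

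Leaving out 1 library gave 954 to 1343 genes for FO KO, 2662 to 7722 for MZ KO, 1 to 24 for FO het, 42 to 4464 for MZ het, 2610.0 to 4781 for MZ WT, 653 to 861 for FO KO-het, 1304 to 1631 for MZ KO-het and 310.0 to 525 for the difference. It gave r of -0.176 to 0.243 for MZ likeness and -0.198 to 0.215 for the MZ score difference. Differences in the immunoglobulin share ran from -0.177 to 0.0475 for FO KO, 0.742 to 0.903 for MZ KO, 0.225 to 0.537 for FO het, 0.401 to 0.611 for MZ het, -0.662 to -0.437 for MZ WT, -0.622 to -0.309 for FO KO-het and 0.198 to 0.413 for MZ KO-het. Of 23232 gene results with 1 library left out, 21985 kept their direction and call and 1223 lost the call, and of 5643 list results 5499 kept it.

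Median scaling, by its constant per comparison, reversed 30 such results with small changes, and quantile normalization 1. In FO KO they were Rpl3 (0.0229), Paics (0.0237), H2-Ob (0.0773) and Cd22 (0.0484). In MZ KO they were Slc2a1 (0.18), Ell2 (0.0828), Noc2l (0.14), Mybbp1a (0.33), Polr1c (0.35), Pfas (0.0242), Cd86 (0.0541), Ier5 (0.19) and Cd24a (0.30). In MZ het they were Yars (0.19), Uvrag (0.25) and Mrpl35 (0.15). In MZ WT they were Acly (0.0668), Pfkp (0.10), Aldoa (0.24), Bnip3l (0.0669), Pck2 (0.0272), Vars (0.26), Cars (0.0718), Gabarap (0.18), Uqcrc1 (0.15), Ndufs1 (0.11), Ndufs7 (0.20), Prps1 (0.20), Psmb6 (0.14) and Cd74 (0.12). It also reversed ribosome biogenesis in FO KO (adjusted p = 0.130). Quantile normalization reversed Cd74 in MZ het (-0.11). A mean of at least 20 TPM reversed immediate early genes and B1 and age-associated genes in MZ KO (adjusted p = 0.707 and 0.593), germinal centre genes in FO het (0.588), mitochondrial ribosomal proteins and myeloid markers in MZ het (0.939 and 0.688) and cholesterol synthesis in the difference (0.932). The background term reversed B cell receptor signalling in MZ KO (adjusted p = 0.785) and secretory translocation, mitochondrial ribosomal proteins and FoxO-associated genes in MZ het (0.974, 0.729 and 0.974).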

Other observations

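The tests of chromosome 14 and of the MZ KO profile and score at 20 TPM were chosen only after the result was seen.

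Some gene groups changed in the KO comparisons without a place above. In FO KO, Scd1, a fatty acid desaturase, fell from 251 to 186 TPM (log2 -0.44 ± 0.08, adjusted p = 0.000376), and it fell from 258 to 212 TPM in MZ KO compared with MZ het (log2 -0.36 ± 0.07, adjusted p = 0.000786). Ccl3, a chemokine of activated B cells, rose from 1.84 to 7.59 TPM in FO KO and from 9.50 to 38.8 TPM in MZ KO. Nfkbid, an NF-kappaB regulator, fell in FO KO from 265 to 155 TPM (log2 -0.78 ± 0.13, adjusted p = 7.44e-05). Pik3cd, the leukocyte PI3K catalytic subunit, rose from 130.0 to 176 TPM in FO KO and from 94.4 to 145 TPM in MZ KO. Among autophagy genes in FO KO 5 of 31 rose and 0 fell, 5 and 0 adjusted over the list alone. At the median, log2 change was 0.03 (adjusted p = 0.0101, or adjusted p = 0.0257 with an estimated correlation). In MZ KO 8 of 31 rose and 3 fell, 8 and 3 adjusted over the list alone. As a list they had a median log2 change of 0.02 (adjusted p = 0.00103, or adjusted p = 0.00446 with an estimated correlation). The mean log2 change was -0.04, although the test called the list higher than other genes. Gabarap, which builds autophagosomes, rose from 376 to 641 TPM in FO KO and from 297 to 514 TPM in MZ KO, and Fnip1, a partner of Flcn, from 5.06 to 7.78 TPM and 5.96 to 11.8 TPM.

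Of glycolysis genes in FO KO, 5 of 21 rose and 0 fell, 6 and 2 adjusted over the list alone, at a median log2 change of -0.03, 0.31 under median scaling and 0.08 under quantile normalization (adjusted p = 0.0178, or adjusted p = 0.147 with an estimated correlation). The test called the list higher than other genes although its median and mean were -0.03 and -0.02. Its preset p was 0.0519 without FO KO 4 and 0.0619 without FO KO 6. Of mitochondrially encoded genes in MZ WT compared with FO WT, 12 of 12 rose and 0 fell, 12 and 0 adjusted over the list alone. List members had a median log2 change of 0.53 (adjusted p = 4.72e-12, or adjusted p = 0.0635 with an estimated correlation). Edem1, which acts in disposal of misfolded proteins, rose in MZ WT from 28.7 to 54.1 TPM (log2 0.95 ± 0.10, adjusted p = 6.29e-09), and Pdia4, a disulfide isomerase, from 225 to 859 TPM.

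The MZ KO profile was compared with that of FO cells over all genes. Across 5863 genes with a mean of at least 20 TPM, MZ KO minus MZ het correlated with FO WT minus MZ WT at r = 0.360, and these share no library. Across all 20513 tested genes r was -0.0462. In that set of genes at 20 TPM, the MZ score of MZ KO was lower than that of MZ het by a difference of -0.383 (exact permutation p = 0.00216, two-sided, the smallest possible, adjusted p = 0.0173). The difference from MZ WT was -0.346, but the MZ WT libraries also chose the genes of the score, which by itself lowers any other MZ group, so it is not used here. Over all genes called between the WT groups the difference from MZ het was -0.273 (exact permutation p = 0.0519, adjusted p = 0.111). That from MZ WT was 0.0954 (exact permutation p = 0.729), of the opposite sign to the value at 20 TPM. A partial shift of MZ KO cells toward the FO profile may underlie the lower MZ genes, but this hypothesis rests on abundant genes alone and stays open.

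Genes that moved alike in both het comparisons lay on chromosome 14 more often than its share. Of 69 genes with an unadjusted p under 0.01 and the same sign in FO and MZ het, 10 were on chromosome 14 where 2.42 would be, a ratio of 4.14 (exact hypergeometric p = 0.000131, one-sided, adjusted p = 0.00262 over 20 chromosomes). This was found by scanning all chromosomes at p limits of 0.01 and 0.05, and the latter gave 19 of 243 genes where 8.51 would be. The genes were Dnajc15, Dok2, Gpr183, Osgep, Psmb5, Rnase6, Rpgrip1, Rps3a2, Sap18 and Supt16. In KO compared with het the chromosome held 0.894 times its share, and in KO compared with WT 25 genes where 22.8 would be (exact hypergeometric p = 0.342, one-sided, adjusted p = 0.852). Dok2 was 4.28 to 11.9 TPM in the 11 WT libraries, 4.78 in MZ KO 1 and at least 13.7 in the other 21 het and KO libraries. Supt16 (chromosome 14, 52160414 to 52197416, minus strand) was 16.1 to 21.0 TPM in WT, 16.0 in MZ KO 1 and at least 28.9 in the others. Tsc1 lies on chromosome 2, so a segment of chromosome 14 that differs between WT and the other mice is a candidate explanation for these genes in the het comparisons. The chromosome had no such excess in KO compared with WT. That result cannot decide the question, since 650 genes moved there and an excess of the size seen in het could be hidden among them. The segment itself was not tested, since only expression values were used.

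The summed TPM of 4 processed pseudogenes, Gm10020, Rpl15-ps2, Gm10704 and Gm8420, was 0 to 13.1 in 9 WT libraries, 249 in FO WT 5, 319.9 in MZ WT 5 and 155 to 613 in the 22 het and KO libraries. They lie on chromosomes 15, 9, 3 and 1, and 91.5%, 74.9%, 0.00% and 37.6% of their 25-base words occur in Rpl15 of chromosome 14. FO and MZ libraries of the same WT number were alike in this sum for 3 of 5 numbers at a limit of 10 TPM and for 5 of 5 at 100 TPM, a limit chosen after the values were seen.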
